A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

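Gene expression was measured in the yeast Saccharomyces cerevisiae on 9 single-colour microarrays, 1 for each of 3 strains (KF7, NBRC1958 and NBRC2018) at each of 3 levels of added succinic acid (0, 20 and 60 g/L). Per the labels, the cells were grown in YPD medium at 35 °C and 200 rpm for 6 hours, total RNA was extracted with Trizol, and biotin-labelled cRNA was hybridized.

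The deposited values are linear intensity values, 1 per probe set and array, which the authors had normalized and summarized. How the arrays were scanned, summarized, background-corrected and normalized is not given in the sources used here. The 9 arrays had nearly equal medians over the yeast genes, so the authors' normalization between arrays was kept. The deposited values ran from 1.78 to 9468, and the analysis used the base 2 logarithm of the value plus an offset of 16.

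The array carried 10928 probe sets. A probe annotation from 2016 paired 5498 of them with 1 S. cerevisiae gene each and 1746 with genes of another organism. A further 213 were controls, 3470 had no gene name and 1 named several genes. Symbols were matched to a reference table of gene names, which updated 12 of them. The 5498 probe sets stood for 5449 genes, and for the 47 genes with several probe sets the probe set with the highest mean was taken. In 8 of these 47 genes the probe sets had opposite signs at 60 against 0 g/L. Genes in the lowest 20% of the mean over all arrays were left out, which removed 1090 genes under a signal of 118 and left 4359 for testing. Of the tested genes, 70 were read by a probe set whose suffix marks it as shared with other sequences.

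Probe sets of the other organism served as the background, and their 95th percentile over all arrays was a signal of 15.1. The number of arrays limits the precision. There was 1 array per strain and dose, so the 3 strains served as the replicates of a dose and the 3 doses as the replicates of a strain. Nothing in the labels says whether arrays came from separate cultures, so the p-values speak only for these samples. For the dose and strain comparisons their error is what remains after strain and dose means are removed. It holds array error and any difference between strains in the response to dose, and it is not the SD printed beside a mean.

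Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust). Strain and dose entered as additive factors, which left 4 residual degrees of freedom, so strain was a block for the dose comparisons. Contrasts were 60 against 0, 20 against 0 and 60 against 20 g/L, and the 3 pairs of strains. Moderated F tests asked whether any dose or any strain differed. A second model with a straight line on dose per strain (3 residual degrees of freedom) tested whether slopes differed between strains. Slopes are given as the log2 change over 60 g/L. P-values were adjusted by the Benjamini-Hochberg method over the 4359 genes, with a threshold of 0.05.

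Before the data were examined, 48 gene lists were fixed from textbook knowledge of yeast regulation, and 45 of them had at least 3 tested members. The lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and limma's fry, which asks whether the genes of a list move on balance in 1 direction, were the alternatives. Counts of list members past the test are given over all genes tested and adjusted over the list alone.

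The genes named in the text were also chosen by a rule fixed in advance. For 60 against 0 g/L these were the 10 largest rises and the 10 largest falls past the test with the same sign in every strain, and up to 4 members of each list past its test or 2 of each other list. For the other comparisons they were the 5 largest in each direction, or the 5 smallest p-values where none passed. A fixed set of genes of acid response, succinate metabolism, flocculation and mating was always included. MSN4, SDH5, MPC2, TIR3, TIR4 and ICL1 were named outside the rule, and other genes named outside it are said to be so where they appear.

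Alternatives fixed in advance were quantile normalization, median centring, no level filter, a filter of the lowest 50%, a filter at the other-organism background, an intensity trend, a robust fit, the mean of a gene's probe sets, and offsets of 1 and 64. Others were a fit with no replicate block or no dose term, a fit of only the arrays compared, and leaving out each array, strain or dose in turn. Dose as a rank was tried for the slopes. Leaving out each array for the gene lists of the KF7 slope was added after the data were seen. Other splits of the arrays into groups of the same sizes were fitted in the same way, all of them or 100 drawn at random.

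The procedure was tested on simulated data with 200 of the 4359 genes changed. For 60 against 0 g/L it recovered 59.7% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or 2, with 11 false among 184 calls. For the slope of KF7 it recovered 4.48%, 41.8% and 100% at sizes of 0.5, 1 and 2, with 11 false among 108 calls. These simulated slopes were straight lines in KF7 alone, with no dose effect in the other strains. A response that bends with dose adds to the error of the slope model, so this recovery does not carry over to bent responses. For KF7 against NBRC1958 it recovered 73.1%, 98.5% and 100%, with 15 false among 196 calls. Of 40 simulated lists of 20 genes, with genes drawn independently, 10 were shifted by 0.5. Each of the 3 list tests recovered all 10, with 2 false calls at the preset correlation, 0 with an estimated correlation and 0 by fry. Figures were drawn with matplotlib 3.10.9. The probe sets with no gene name, those of the other organism and the controls were left out of the comparisons because they stand for no named yeast gene.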

Results

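The data comprise 9 arrays, 1 for each of the S. cerevisiae strains KF7, NBRC1958 and NBRC2018 grown with 0, 20 or 60 g/L succinic acid, a dicarboxylic acid of the citric acid cycle. Each dose therefore had 3 arrays, 1 per strain. The stated purpose was to examine how yeast responds to stress from succinic acid. The arrays were alike in depth. The median signal over S. cerevisiae genes ran from 294 to 311 arbitrary units, and between 96.7% and 97.5% of the 5449 genes lay above the 95th percentile of the other-organism probe sets of the same array, which was 14.7 to 15.9. Over the 4359 genes tested, strain accounted for 51.8% of the sum of squares, dose for 34.2% and the remainder for 14.0%. Some difference between the 3 doses was found for 724 genes. This count was 293, 359 and 315 without the NBRC1958 array at 0, 20 and 60 g/L, 431 and 260 without the NBRC2018 array at 20 and 60 g/L, and 466 without the KF7 array at 0 g/L.

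At 60 against 0 g/L, 17 of 26 tested heat shock genes rose, and 10 of 13 thiamine genes and 11 of 18 purine genes fell. None of these 3 lists passed with an estimated correlation (adjusted p = 0.41, 0.64 and 0.64). BTN2 (YGR142W), which sorts misfolded proteins, rose from a signal of 764 ± 681 at 0 g/L to 6329 ± 1632 at 60 g/L (mean ± SD, n = 3), a log2 difference of 3.34 (adjusted p = 0.0022). The stress-induced Hsp70 gene SSA4 (YER103W) rose from 422 ± 188 to 3315 ± 1945. STL1 (YDR536W), a glycerol importer, rose from 102 ± 102 to 933 ± 595. GCV1 (YDR019C), a subunit of the glycine cleavage complex, fell from 1310 ± 116 to 237 ± 74.4, and GCV2 (YMR189W) of the same complex fell from 927 ± 42.5 to 225 ± 97.5. In all, 995 of 4359 genes passed the test at 60 against 0 g/L, 378 higher and 617 lower, and 994 of them moved the same way in all 3 strains. The test counts disagreement between strains as error, so genes past it tend to agree in sign. The 994 are therefore not separate support for a shared response. Of the 995, 79 were at least 2-fold higher and 40 at least 2-fold lower. More genes were higher than lower also without the NBRC1958 array at 0 g/L (109 and 108), without NBRC1958 (63 and 35) and without NBRC2018 (200 and 172). With median centring of the arrays the split was 452 higher and 486 lower, and with quantile normalization 420 and 501. Leaving out the NBRC1958 array at 0 g/L lowered the count to 217, and the count was 543 without the KF7 array at 0 g/L, 653 without the NBRC1958 array at 60 g/L and 644 without the NBRC2018 array at 60 g/L.

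**Figure D1:**
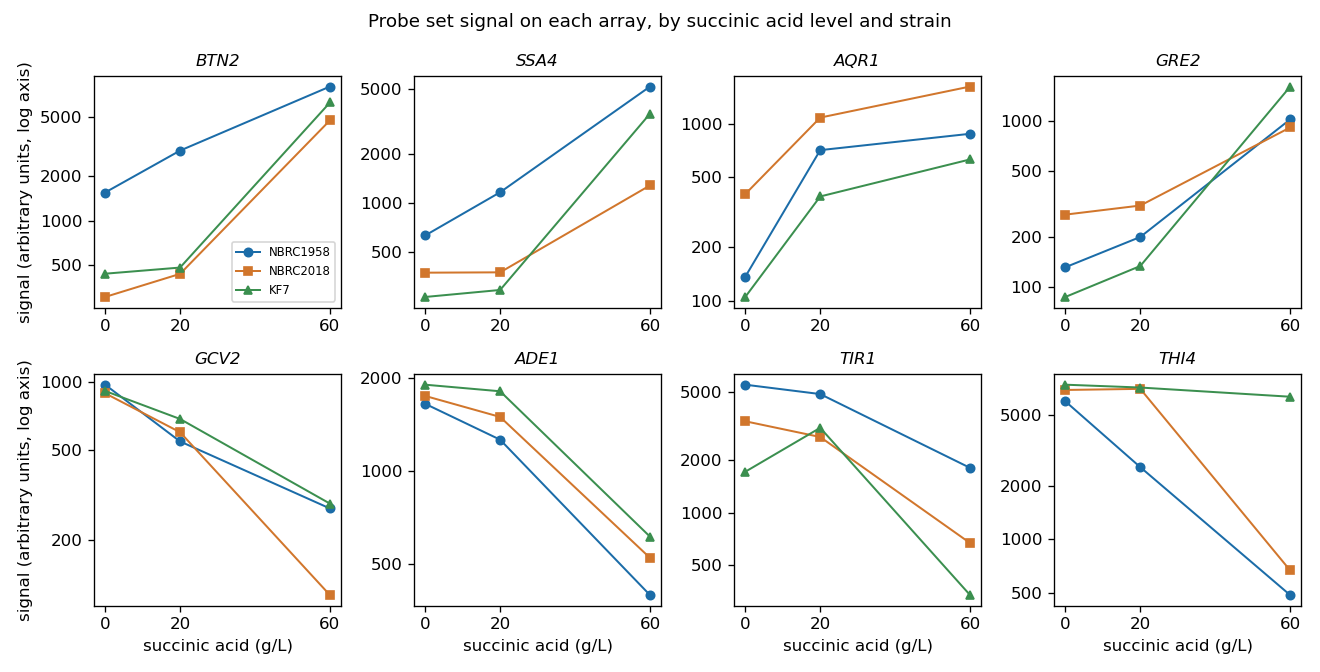
Signal (arbitrary units, log axis) against succinic acid (g/L) for 8 genes, with 1 point per array and 1 line per strain. BTN2 stood at 4740 or more on each array at 60 g/L and at 1547 or less on each array at 0 g/L, whereas THI4 at 60 g/L was 483 in NBRC1958, 665 in NBRC2018 and 6336 in KF7.

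The other large rises at 60 g/L included YHR033W (log2 difference 3.94) and YGR035C (3.31), for which no function is given here. APJ1, a J-domain chaperone, rose by 2.83 with a standard error of 0.163, and GRE2, a methylglyoxal reductase, rose by 2.83. FDH1, a formate dehydrogenase, rose by 2.61, PHM8, a lysophosphatidic acid phosphatase, by 2.58, and PCK1, the gluconeogenic phosphoenolpyruvate carboxykinase, by 2.50. The large falls were THI22 (log2 difference -2.71), SNZ3 (-2.58), THI4 (-2.39), SNO3 (-2.20), PET18 (-2.04) and THI13 (-2.004), and the cell wall mannoproteins TIR1 (-2.07) and TIR2 (-1.98). THI13, THI22, SNZ3 and SNO3 belong to families of near-identical genes, so their probe sets may read relatives as well. THI4 did not pass the test when either NBRC1958 array or either NBRC2018 array at 0 or 60 g/L was left out, with adjusted p between 0.081 and 0.15.

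Of 26 tested members of the list of targets of the heat shock factor Hsf1, 17 rose and none fell, and adjusted over the list alone 22 rose and 1 fell. The list's median log2 difference was 0.94. Besides BTN2 and SSA4, HSP78, a mitochondrial disaggregase, rose by 2.19 and CUR1, a relative of BTN2, by 2.17. The list passed by camera (adjusted p = 5.5e-14) and fry (0.0051), and had an adjusted p = 0.41 with an estimated correlation. Of 34 tested genes of the general stress response (targets of Msn2 and Msn4), 8 rose, 1 fell and 25 did not pass, and adjusted over the list alone 11 rose and 2 fell. SSA4 (2.80) belongs to this list as well as the heat shock list, so the 2 lists are not separate. SIP18 rose by 1.29, SOL4 by 1.09 and the disaggregase HSP104 by 1.01, and MSN4 itself fell by 0.76. The adjusted p of this list was 0.0024 by camera and 0.78 with an estimated correlation. The membrane stress genes HSP12 (0.90, adjusted p = 0.058) and HSP30 (1.05, adjusted p = 0.067) did not pass. Of 19 trehalose and glycogen genes only TPS2, of trehalose synthesis, passed, at 0.53, and none passed adjusted over the list alone.

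Exporters and genes of acid response changed in part. Of 16 tested multidrug transporters and related genes, 7 rose and none fell, and 8 rose when adjusted over the list alone. AQR1, a transporter of the major facilitator family linked to acid resistance, rose from 214 ± 162 to 1046 ± 520, a log2 difference of 2.32 (adjusted p = 0.00023). TPO4, a polyamine exporter, rose by 1.46, and the drug pumps PDR5 and SNQ2 by 0.98 and 0.85. This list passed by camera (adjusted p = 1.8e-05) and fry (0.00071), and its adjusted p = 0.30 with an estimated correlation. Of 12 targets of the weak acid regulator Haa1, 5 rose and none fell, and 5 did so adjusted over the list alone (camera adjusted p = 0.021, and adjusted p = 0.64 with an estimated correlation). They included PHM8, the cell wall gene SPI1 (1.22), the ceramidase gene YPC1 (0.74) and the inositol monophosphatase gene INM1 (0.65). HAA1 itself had a log2 difference of -0.06 and its target TPO2 one of 0.25, and neither passed. The weak acid pump PDR12 (0.55, adjusted p = 0.072) and its regulator WAR1 (0.33, adjusted p = 0.051) did not pass over all genes, and 2 of the 3 genes of that list rose when adjusted over the list alone. The plasma membrane proton pump gene PMA1 had a log2 difference of 0.02 (standard error 0.0815). TPO3 lay below the level filter.

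Of 15 tested glycerol and osmotic stress genes, 6 rose, 9 did not pass and none fell, and adjusted over the list alone 8 rose and 3 fell. STL1 and GRE2 rose most, and GPP2 and GPD2, enzymes of glycerol synthesis, rose by 0.70 and 0.66. The list passed by camera (adjusted p = 0.030) and had an adjusted p = 0.64 with an estimated correlation and 0.068 by fry.

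Some genes of succinate metabolism itself passed at 60 against 0 g/L, where 22.8% of all tested genes passed. Of 8 genes of succinate dehydrogenase, the enzyme that oxidizes succinate, 2 assembly factor genes fell, SDH8 (-0.77) and SDH5 (-0.42), and adjusted over the list alone 1 rose and 3 fell. The subunit genes SDH1 (-0.16), SDH2 (-0.42), SDH3 (0.25) and SDH4 (-0.29) did not pass. SDH6 of the same list (0.46, adjusted p = 0.063) and the fumarase gene FUM1 (0.04) did not pass either. Among transporters, the mitochondrial dicarboxylate carrier DIC1 (-0.05) and the carboxylate importer JEN1 (0.01, standard error 0.558) did not pass, and SFC1 lay below the level filter. Of 12 dicarboxylate and mitochondrial carriers, 3 rose, also adjusted over the list alone: the pyruvate carrier genes MPC3 (1.496) and MPC2 (0.64) and the oxodicarboxylate carrier ODC1 (0.74). Of 17 citric acid cycle genes only MDH1 passed, at -0.45, and it did not pass with median centring (adjusted p = 0.0501) or without any of 6 single arrays. No gene of this list passed adjusted over the list alone. SDH8 did not pass without the NBRC1958 array at 0 g/L (adjusted p = 0.081) or without 1 of 3 further arrays.

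Of 11 tested genes of the glyoxylate cycle and gluconeogenesis 2 rose, PCK1 and the cytosolic malate dehydrogenase gene MDH2 (0.80), and 2 rose adjusted over the list alone. Of 6 tested maltose, sucrose and galactose genes 3 rose, the isomaltase gene IMA1 (1.37), the maltase gene MAL32 (1.35) and the maltose permease gene MAL31 (0.74), and 4 rose adjusted over the list alone. The first of these lists had an adjusted p = 0.0093 by camera and 0.096 by fry, the other 0.0013 and 0.029, and both had an adjusted p = 0.64 with an estimated correlation. HXT5, a hexose transporter gene, rose by 2.18 from 70.6 ± 32.4 to 402 ± 249.6. TKL2 (1.60) and NQM1 (1.22), minor isoforms of the pentose phosphate pathway, also rose. PDC5, a minor pyruvate decarboxylase, fell by 1.53, and PYK2, a minor pyruvate kinase, fell by 0.83.

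Of 18 purine synthesis genes, a list that includes folate-linked enzymes, 11 fell and none rose, and 13 fell adjusted over the list alone. These included MTD1, a folate dehydrogenase (-1.95), the purine gene ADE1 (-1.78), SHM2, a serine hydroxymethyltransferase (-1.61), and the IMP dehydrogenase gene IMD2 (-1.61). Of 13 tested thiamine genes 10 fell and none rose, and 12 fell adjusted over the list alone, with a list median of -1.49. Of 46 tested amino acid genes under Gcn4, 11 fell and 1 rose (adjusted over the list alone, 17 and 3). Examples were ARG4 (-1.10), HIS4 (-0.98) and ARG1 (-0.91), and the serine synthesis gene SER3 rose by 1.16. Of 23 methionine and sulfate genes 9 fell and 2 rose (10 and 3 adjusted over the list alone), among them MET3 (-1.65), MET6 (-1.48) and MET17 (-1.40), while the regulator gene MET28 rose by 1.39. All 4 lists passed by camera, with adjusted p of 1.6e-05, 2.5e-05, 0.018 and 0.047 in this order, and had an adjusted p between 0.64 and 0.74 with an estimated correlation. By fry the purine list passed (adjusted p = 0.0051) and the other lists did not (0.068, 0.074 and 0.11).

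Genes of nitrogen catabolite repression, which are kept low on good nitrogen sources, included 4 that rose and none that fell among 17 tested, and 5 rose adjusted over the list alone. Arginine breakdown genes CAR1 (1.54) and CAR2 (0.85), the ammonium permease gene MEP1 (0.99) and the amino acid permease gene GAP1 (0.80) were the 4. Of 19 iron regulon genes 4 rose and none fell, and 5 rose adjusted over the list alone, among them the siderophore-binding FIT1 (1.45) and the siderophore importer SIT1 (0.82). The ferric reductase gene FRE1 (0.77) and the biotin importer VHT1 (0.67) were the others. Camera gave an adjusted p of 0.00033 for the nitrogen list and 0.038 for the iron list, and both had an adjusted p = 0.64 with an estimated correlation. The iron list had an adjusted p = 0.073 with quantile normalization.

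Of 9 histone genes 5 fell, among them the linker histone gene HHO1 (-0.82) and HTA1 (-0.66), HHT1 (-0.61) and HTB1 (-0.39), and all 9 fell adjusted over the list alone. Of 32 cell cycle genes 10 fell and none rose (15 adjusted over the list alone), including the daughter cell separation genes SCW11 (-1.37), DSE2 (-1.24) and DSE1 (-0.85) and the cyclin gene PCL9 (-0.94). Of 32 proteasome genes 9 fell, such as RPT4 (-0.60), PRE1 (-0.56) and RPT5 (-0.45), while RPN4, their transcription factor, rose by 0.67, and adjusted over the list alone 17 fell and 1 rose. Of 127 ribosomal protein genes only 3 passed, all higher (RPL27A 0.38, RPS25B 0.36 and RPS20 0.35), and none passed adjusted over the list alone. Camera called the first 3 of these lists downward (adjusted p = 0.0017, 0.012 and 0.0017) and the ribosomal protein list upward (adjusted p = 3.7e-06, median 0.13), and gave each an adjusted p between 0.64 and 0.78 with an estimated correlation. By fry the histone list (adjusted p = 0.037) and the proteasome list (0.048) passed.

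Cell surface and membrane genes changed in both directions. Of 12 cell wall mannoproteins and hypoxic genes of the DAN/TIR list 6 fell, including TIR3 (-1.26) and TIR4 (-1.14), and 1, the cytochrome oxidase gene COX5B (0.45), rose. Adjusted over the list alone 7 fell and 1 rose. This list passed by fry (adjusted p = 0.0051) but not by camera (0.094, and adjusted p = 0.64 with an estimated correlation). Of 29 cell wall integrity genes 4 rose and 6 fell, also adjusted over the list alone, with the glucan synthase gene GSC2 at 0.79 and the wall protein gene PIR1 at -0.84. Of 25 ergosterol genes 3 fell and none rose, also adjusted over the list alone: ERG6 (-0.57), ERG24 (-0.56) and ERG11 (-0.37). The ergosterol list had an adjusted p = 0.038 by camera, 0.052 with quantile normalization and adjusted p = 0.78 with an estimated correlation. None of 6 tested flocculation genes passed, with FLO1 at -0.60, FLO9 at -0.32 and FLO11 at -0.09, and FLO8 and FLO10 lay below the level filter. FLO11 alone among the named genes was past the test with the opposite sign in 1 alternative, at 0.46 (adjusted p = 0.021) without the NBRC1958 array at 60 g/L.

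The mating genes STE2, STE3 and MFA1 had mean signals of 37.4, 11.8 and 62.4 at 0 g/L and 33.9, 11.1 and 72.0 at 60 g/L, all below the level filter. Among meiosis genes, the kinase gene IME2 rose from 92.0 ± 7.97 to 243 ± 80.6, a log2 difference of 1.21 (adjusted p = 0.0083). IME2 was chosen for naming after its values were seen.

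**Figure D2:**
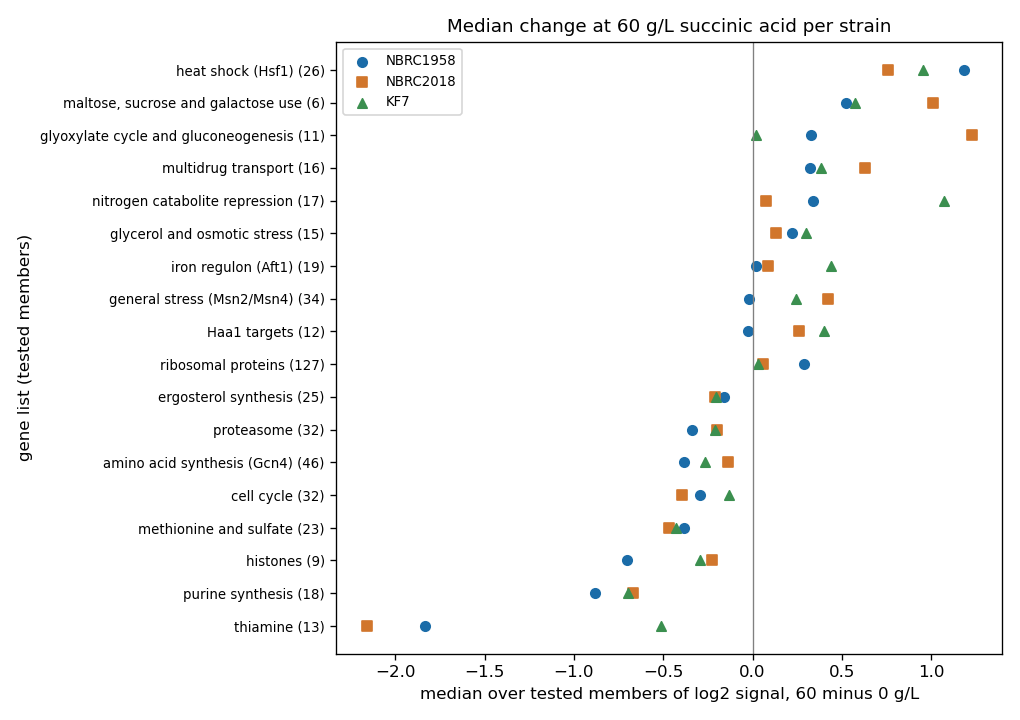
Median over tested members of the log2 difference at 60 against 0 g/L (x axis) for the 18 gene lists past the camera test (y axis, tested members in parentheses), with 1 symbol per strain. The heat shock list had medians of 1.18 in NBRC1958, 0.76 in NBRC2018 and 0.96 in KF7, and the thiamine list -1.83, -2.16 and -0.51, and none of the 18 passed with an estimated correlation.

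In total 18 of 45 lists passed by camera at 60 against 0 g/L, 10 upward and 8 downward. With an estimated correlation none passed (limma camera, smallest adjusted p = 0.304), whereas at unadjusted p under 0.05 over genes 1758 of 4359 genes passed against 218 expected by chance. By fry 7 lists passed, 6 of them among the 18. Splits of the same 6 arrays into other groups of 3 gave up to 25 lists past the camera test. Without NBRC2018 11 lists passed.

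The comparison of 20 with 0 g/L asks what a lower dose does. Only AQR1 (YNL065W) passed, rising from 214 ± 162 to 729 ± 349, a log2 difference of 1.801 (adjusted p = 0.011). Its log2 differences were 2.25 in NBRC1958, 1.40 in NBRC2018 and 1.74 in KF7. The genes with the next smallest p-values were INM1 (0.77), VID24 (0.71), RIM8 (-0.51), GGC1 (-0.53) and ARG1 (-0.82), each with an adjusted p of 0.95. At unadjusted p under 0.05 there were 158 genes against 218 expected by chance. AQR1 did not pass without the NBRC1958 array at 0 g/L (adjusted p = 0.057), the NBRC2018 array at 20 g/L (0.052), or the KF7 array at 0 g/L (0.12) or 20 g/L (0.13). With only the 6 arrays compared 6 genes passed, 3 higher and 3 lower.

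By camera 18 lists passed at 20 against 0 g/L, 7 upward and 11 downward, although none of their members except AQR1 passed over all genes, and 1 member each of the Haa1, osmotic and multidrug lists rose adjusted over the list alone. The medians were small. The 46 amino acid genes under Gcn4 had a median of -0.13 and the 51 ribosome biogenesis genes one of 0.14, and no member of either passed adjusted over the list alone. The 22 respiratory chain genes had a median of -0.12, with -0.25 in NBRC1958, 0.15 in NBRC2018 and -0.25 in KF7. No list passed with an estimated correlation (smallest adjusted p = 0.680) or by fry. Other splits of the 6 arrays gave up to 22 lists.

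Between 20 and 60 g/L, 695 genes passed, 252 higher and 443 lower. FDH1 rose by 2.94 from 302 ± 426 to 1522 ± 1155, YHR033W by 2.86, BTN2 by 2.82 and APJ1 by 2.66. YGR035C rose by 3.25. TIR1 fell by 2.19 from 3552 ± 1127 to 936 ± 775, and THI22 (-2.12), SNZ3 (-2.10) and GCV1 (-1.89) fell too. THI73, a plasma membrane carrier of the thiamine regulon, fell by 1.95. AQR1, which had risen by 20 g/L, had a log2 difference of 0.52 between 20 and 60 g/L (adjusted p = 0.055). The split was 309 higher and 331 lower with quantile normalization and 316 and 302 with median centring. Among genes at least 2-fold different it was 66 and 27, and it also turned without the NBRC2018 array at 20 g/L (91 and 74) or 60 g/L (183 and 144), without NBRC1958 (32 and 23) and without NBRC2018 (54 and 25). The count was 128 without the NBRC1958 array at 20 g/L, 165 without the NBRC2018 array and 229 without the KF7 array at that dose, and 294 and 327 without the NBRC1958 and NBRC2018 arrays at 60 g/L.

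The gene groups at 60 against 20 g/L were as follows. Of 26 heat shock genes 15 rose (21 adjusted over the list alone), of 18 purine genes 11 fell (12), of 13 thiamine genes 9 fell (13), and of 17 nitrogen catabolite genes 6 rose (7). Of 16 multidrug genes 5 rose (6) and of 32 cell cycle genes 12 fell (14). By camera 18 lists passed, 11 upward and 7 downward, none of them with an estimated correlation (smallest adjusted p = 0.330). By fry 6 passed, among them the heat shock (adjusted p = 0.0072), purine (0.0072) and multidrug lists (0.0032). Other splits of these 6 arrays gave up to 24 lists.

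Strain comparisons ask how the backgrounds differ whatever the dose, with the 3 doses as replicates. In all 1577 genes differed between strains, a count that was 729 and 656 without the NBRC1958 array at 0 and 20 g/L, 892, 1024 and 1031 without the NBRC2018 arrays at 0, 20 and 60 g/L, and 994 without the KF7 array at 0 g/L. A sequence difference between a strain and the probes could also lower a signal, and the genomes of the strains were not used here. KF7 differed from NBRC1958 in 833 genes, 412 higher and 421 lower, and in 62 and 69 by at least 2-fold. This near-even split turned in 8 alternatives, among them those without the KF7 array at 0 g/L (213 and 189) or 20 g/L (218 and 204), the NBRC1958 array at 0 g/L (167 and 162) or the NBRC2018 array at 20 g/L (319 and 316). PHO3, an acid phosphatase, stood at 2963 ± 647 in KF7 and 112 ± 8.37 in NBRC1958 (mean ± SD, n = 3), a log2 difference of 4.51. ALD3, an aldehyde dehydrogenase, was higher in KF7 by 3.30, the invertase gene SUC2 by 3.16, YNR071C by 2.99 and FET3, a copper-dependent iron oxidase, by 2.88. CHL4, a kinetochore gene, stood at 32.6 ± 2.39 in KF7 and 324 ± 31.5 in NBRC1958 (log2 difference -2.80, adjusted p = 9.2e-06). SGA1, a sporulation glucoamylase (-3.04), NCA3 (-3.00), PHM7 (-2.92) and IMA1 (-2.80) were also lower in KF7. Of 19 iron regulon genes 11 were higher in KF7 and none lower, of 25 ergosterol genes 13 were higher and 1 lower, and of 26 heat shock genes 1 was higher and 11 lower. Adjusted over the list alone these counts were 14 and 1, 17 and 1, and 1 and 17. The 9 lists past camera had an adjusted p = 0.88 with an estimated correlation, and fry called only the iron list (adjusted p = 0.0355). The count of genes was 329 and 302 without the NBRC1958 array at 0 and 20 g/L, and 402 and 422 without the KF7 array at 0 and 20 g/L.

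KF7 differed from NBRC2018 in 716 genes, 311 higher and 405 lower. By at least 2-fold more were higher (88) than lower (35). The split also turned without the NBRC2018 array at 0 g/L (131 and 128), 20 g/L (178 and 173) or 60 g/L (150 and 147), without the KF7 array at 0 g/L (133 and 108), and without the 3 arrays at 0 g/L (61 and 43) or 20 g/L (85 and 54). It was 170 and 167 with the lowest 50% left out and 230 and 228 with only the 6 arrays compared. YNR071C was higher in KF7 by 3.96, the drug transporter gene QDR2 by 3.29, DSF1, a mannitol dehydrogenase, by 3.25, SUC2 by 3.21 and the urea transporter gene DUR3 by 2.96. QDR2 stood at 986 ± 219 in KF7 and 89.7 ± 40.6 in NBRC2018. Lower in KF7 were CHL4 (-2.35), IMA1 (-2.21), ARO10 (-2.16) and ARO9 (-2.12), both of aromatic amino acid breakdown, and YDL124W (-1.93). Of 19 iron regulon genes 13 were higher and 1 lower in KF7, of 17 nitrogen catabolite genes 9 were higher, of 12 DAN/TIR genes 7 were higher and of 29 cell wall integrity genes 9 were lower and 1 higher. Adjusted over the list alone these were 13 and 3, 11, 7, and 13 and 1. These 4 lists also passed by fry (adjusted p = 0.021, 0.029, 0.0051 and 0.0265), and all 19 lists past camera had an adjusted p of 0.459 or more with an estimated correlation. The count of genes was 458 without the NBRC1958 array at 20 g/L, 259, 351 and 297 without the NBRC2018 arrays at 0, 20 and 60 g/L, and 241 and 381 without the KF7 arrays at 0 and 60 g/L.

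NBRC2018 differed from NBRC1958 in 1214 genes, 711 higher and 503 lower. By at least 2-fold 27 were higher and 97 lower. More were lower also without the NBRC1958 array at 0 g/L (197 higher and 209 lower), the NBRC2018 array at 0 g/L (191 and 241), or the 3 arrays at 0 g/L (58 and 121) or 20 g/L (49 and 97). FLO11, the adhesin of pseudohyphal growth, stood at 1931 ± 792 in NBRC1958 and 97.1 ± 22.8 in NBRC2018 (log2 difference -4.02, adjusted p = 0.00083), and the flocculin gene FLO1 was lower in NBRC2018 by a difference of -3.08. SGA1 (-3.66), NCA3 (-3.64) and FDH1 (-3.59) were lower too. PHO3 was higher in NBRC2018 by 4.16, HBN1 by 1.91, the small heat shock gene HSP26 by 1.73, YML131W by 1.57 and ALD3 by 1.38. Of 127 ribosomal protein genes 56 were higher in NBRC2018 and none lower, and 84 were higher adjusted over the list alone. Of 34 general stress genes 2 were higher and 22 lower (2 and 24), of 12 DAN/TIR genes 1 was higher and 10 lower (1 and 10) and of 6 flocculation genes 4 were lower (5). Of these lists the DAN/TIR (adjusted p = 0.0024) and flocculation (0.0066) lists passed by fry, and all 18 lists past camera had an adjusted p of 0.360 or more with an estimated correlation. HSP26 did not pass with only the 6 arrays compared (adjusted p = 0.056). The count of genes was 406 and 395 without the NBRC1958 arrays at 0 and 20 g/L, and 432, 718 and 625 without the NBRC2018 arrays at 0, 20 and 60 g/L.

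The size of the response to 60 g/L differed in number of genes between the strains, with 1 array per strain and dose and so no test. At least 2-fold differences from the 0 g/L array of the same strain were seen for 288 genes in NBRC1958 (161 higher, 127 lower), 171 in NBRC2018 (103 and 68) and 140 in KF7 (97 and 43). At 20 g/L the numbers were 21, 8 and 34. In all 3 strains 34 genes were at least 2-fold higher at 60 g/L and 16 at least 2-fold lower. Across the 4359 genes, which are not independent replicates, the log2 differences at 60 g/L of NBRC1958 and NBRC2018 had a Pearson r of 0.678 and a Spearman rho of 0.579. For NBRC1958 and KF7 these were 0.621 and 0.588, and for NBRC2018 and KF7 0.579 and 0.538. At 20 g/L the Pearson r values of the same 3 pairs were 0.0572, 0.439 and -0.140, and the Spearman rho values -0.0518, 0.453 and -0.177.

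Whether the response to dose differs between strains was tested with a slope per strain. The genes with the smallest p-values for KF7 against the mean of the other strains were HXT2, a glucose transporter (-3.97 over 60 g/L), the acetaldehyde dehydrogenase gene ALD6 (-1.97), IRC7 (1.66), the nitrogen regulator gene GAT1 (1.19) and PAU2 (1.01). Each had an adjusted p of 0.407. HXT2 signals went from 190 to 899 in NBRC1958, from 607 to 957 in NBRC2018 and from 1929 to 319 in KF7 between 0 and 60 g/L. By limma 0 genes passed for KF7 and 0 for any difference of slopes, with 299 and 421 genes at unadjusted p under 0.05 against 218 expected by chance. Without the KF7 array at 0 g/L 3 genes passed for KF7, and 1 gene passed without the NBRC2018 array at 0 or at 20 g/L. Of the gene lists, 15 passed by camera for the KF7 slope, but none with an estimated correlation (smallest adjusted p = 0.864) or by fry. Thiamine led with a median difference of 1.56, and 7 of 13 thiamine genes passed adjusted over the list alone. The thiamine median was 0.19 without the NBRC2018 array at 60 g/L, where the NBRC2018 line rests on 0 and 20 g/L alone.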

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

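The tests of the thiamine genes, of a short variant in the reporter sets, of a later growth stage, of scaling by the ribosome biogenesis list and of slope lists with an array left out were chosen only after the results were seen, whereas those of low hybridization, of scaling by quantile normalization and of other splits were written before. The patterns that the hybridization and scaling tests address were themselves found in these data.

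The slope on dose differed between KF7 and the mean of the other strains for 15 gene lists by camera at the preset correlation, and for 0 lists with an estimated correlation (adjusted p of 0.864 or more) or by fry. The median differences of slope over 60 g/L were 1.56 for thiamine, 0.65 for the PAU genes, 0.58 for nitrogen catabolite repression, 0.26 for the iron regulon, 0.22 for autophagy and 0.21 for the cell cycle. They were -0.52 for the glyoxylate cycle and gluconeogenesis, -0.39 for the phosphate regulon, -0.37 for acetate and aldehyde genes, -0.36 for the respiratory chain and -0.32 for peroxisome genes. For dicarboxylate and mitochondrial carriers the median was -0.30, for ribosome biogenesis -0.16, for ribosomal proteins -0.15 and for translation factors -0.12. Of 100 splits of the arrays 46 gave as many lists (real 15, highest other 23), so chance cannot be excluded for this count.

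Single arrays moved many of these list medians. Without the KF7 array at 0 g/L 8 lists were not called, the glyoxylate cycle (-0.25), carriers (-0.08), the respiratory chain (-0.07), acetate (-0.11), peroxisome genes (0.15), the phosphate regulon (-0.27), iron (0.21) and the cell cycle (0.02). Ribosome biogenesis (-0.66), translation factors (-0.30), nitrogen (1.27) and autophagy (0.60) stayed called there and moved by over 1.5-fold. Without the KF7 array at 20 g/L iron (0.29) and autophagy (0.18) were not called and ribosome biogenesis stood at -0.09. Without the KF7 array at 60 g/L, where the KF7 line rests on 0 and 20 g/L alone, ribosome biogenesis (1.03), nitrogen (-0.82) and autophagy (-0.82) were called in the opposite direction, and ribosomal proteins (-0.04), translation factors (0.18), iron (0.45) and PAU genes (0.67) were not called. The others there were larger, the glyoxylate cycle at -1.48, carriers at -0.80, the respiratory chain at -1.09, acetate at -1.48, peroxisome genes at -1.29, the phosphate regulon at -0.71, thiamine at 2.45 and the cell cycle at 0.72.

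With the NBRC1958 array at 0 g/L left out, the glyoxylate cycle (-0.56), ribosome biogenesis (-0.08), translation factors (-0.08), nitrogen (0.52), iron (0.39) and autophagy (0.22) were not called, and acetate (-0.57) and ribosomal proteins (-0.09) moved. With that strain's array at 60 g/L left out, carriers (-0.28), the respiratory chain (0.08), acetate (-0.05), peroxisome genes (-0.02) and the cell cycle (0.11) were not called. Ribosomal proteins (-0.32), ribosome biogenesis (-0.38), translation factors (-0.27), nitrogen (0.93) and autophagy (0.34) were then larger. For NBRC2018 at 0 g/L the lists not called were peroxisome genes (-0.26) and nitrogen (0.46), and iron (0.41) and autophagy (0.35) were larger. For NBRC2018 at 60 g/L 10 lists were not called, carriers (-0.14), acetate (-0.28), peroxisome genes (-0.38), ribosomal proteins (-0.07), ribosome biogenesis (-0.18), translation factors (-0.08), iron (0.10), the phosphate regulon (-0.18), the cell cycle (0.07) and autophagy (0.18), while thiamine (0.19) and PAU genes (0.43) were smaller. The NBRC arrays at 20 g/L changed none of the 15 calls. As for KF7, an NBRC strain without its array at 60 g/L has a line that rests on 0 and 20 g/L alone.

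Thiamine genes fell less in KF7 than in the other strains, with list medians at 60 against 0 g/L of -0.51 in KF7, -1.83 in NBRC1958 and -2.16 in NBRC2018. The THI4 signal at 0, 20 and 60 g/L was 7408, 7140 and 6336 in KF7, 5971, 2542 and 483 in NBRC1958, and 6917, 7018 and 665 in NBRC2018. Near-identical gene copies are argued against only as far as probe set suffixes mark sharing. The 8 members with no such suffix, with THI20, THI21 and THI22 left out, had a median slope difference of 1.16 (standard error 0.362). A signal ceiling is argued against by the 6 members of lower signal (1.16, standard error 0.304). Both groups came from the same list and gave the same median, so they are not 2 separate arguments. Neither was repeated without the NBRC2018 array at 60 g/L. A wrong dose label on the KF7 array at 60 g/L is argued against by its heat shock list (median 0.956, standard error 0.208, 26 genes). These standard errors are over genes read on the same arrays, so they do not measure the spread between arrays or cultures. The list's median slope difference was 1.56 with all arrays and 0.19 without the NBRC2018 array at 60 g/L. In the latter fit the NBRC2018 line rests on 0 and 20 g/L alone. Without the NBRC1958 array at 60 g/L, where the same holds for NBRC1958, it was 1.59. A difference between the strains may remain as a hypothesis, with an adjusted p = 0.71 by fry and adjusted p = 0.86 with an estimated correlation.

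Of the control probe sets, 5 reporter sets, all named after the same sequence entry, gave a lower signal in KF7 than in the NBRC strains. Their means over the 6 NBRC arrays were 26.1, 123, 1922, 535.9 and 1436, and over the 3 KF7 arrays 2.71, 11.4, 167, 18.7 and 17.5. Low hybridization of the KF7 arrays is argued against by the other 131 control sets (median log2 difference 0.00915, SD 0.120). All 5 were lower by over 1 on the log2 scale, which a short sequence variant under only 1 of the sets would not give. Whether the sets overlap, so that 1 variant lies under several, was not examined. The sets were also looked at because they were low, so a short variant in KF7 stays open. The sequences these sets read were not examined here, so a sequence that the NBRC strains carry and KF7 lacks stays open too, untested, though the third set in KF7 was still above the other-organism probe sets.

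Among probe sets with no gene name, 161 lay above the level filter and 36 of them passed the test at 60 against 0 g/L, 16 higher and 20 lower. These 161 were fitted and adjusted on their own. Of the named genes tested, 22.8% passed, so the unnamed sets do not stand out.

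Glucose-repressed genes were high on the KF7 array at 0 g/L. JEN1 there had a signal of 2120 against 487 at 20 g/L and 550.5 at 60 g/L, and the isocitrate lyase gene ICL1 1376 against 286 and 426. A later growth stage of that culture may be the source and stays open, since the 33 glyoxylate and respiratory chain genes had a median of -0.247 at 20 against 0 g/L in KF7 (standard error 0.0958) and the 51 ribosome biogenesis genes one of 0.333 (standard error 0.0245). Scaling of the whole array as the only cause is argued against by that rise of 0.333, since a bright array would lower every list, while the glyoxylate median after quantile normalization (-0.345, standard error 0.286, 11 genes) was too uncertain to decide. The standard errors here are over genes of the same arrays and do not measure the spread between arrays. With 1 array per strain and dose, an effect of this single array and a strain difference cannot be told apart.

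Other splits of the arrays were fitted for each count. For pairs of doses or strains 10 splits exist, which are too few for a share under 0.05. The real split gave 995 genes at 60 against 0 g/L, 695 at 60 against 20 g/L, 833 for KF7 against NBRC1958 and 716 for KF7 against NBRC2018 (highest other 0 in each, so 1 of 10 was as large), and 1214 for NBRC2018 against NBRC1958 (highest other 1). At 20 against 0 g/L it gave 1 gene and the highest other 3 (2 of 10 as large). For lists the real and highest other values were 18 and 25 at 60 against 0 g/L (2 of 10 as large), 18 and 22 at 20 against 0 g/L (3), 18 and 24 at 60 against 20 g/L (5), 9 and 18 for KF7 against NBRC1958 (8), 19 and 20 for KF7 against NBRC2018 (3), and 18 and 25 for NBRC2018 against NBRC1958 (2). For any difference between doses, 2 of the 88 drawn splits that could be fitted were as large (real 724, highest other 786), a share under 0.05. The drawn splits also exchange arrays between strains, which differed more than the doses did, so this share does not exclude chance. Within strains 2 of 36 were as large, a share above 0.05, and the higher one exchanged only the NBRC2018 arrays at 0 and 20 g/L. The splits that kept the 3 arrays at 60 g/L together gave 786, 724, 519 and 454 genes, and the others within strains at most 2. For any difference between strains 1 of 89 was as large (real 1577, highest other 64) and within doses 1 of 36 (highest other 32), both shares under 0.05. No smaller share could be reached with 36 splits. Such splits also cannot tell strain from anything else that the arrays of a strain shared. For slopes the real value was 0 and no split could be smaller (36 of 36 and 100 of 100 as large, highest other 441 and 582), with 421 and 299 genes at unadjusted p under 0.05 by limma.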

How the results depend on the processing

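Leaving out each array for the lists of the KF7 slope was the alternative chosen after the data were seen. Of 3321 values of 140 named genes under the alternatives at 60 against 0 g/L, 2780 kept direction and side of the threshold, 509 lost the test, 31 gained it and 1 reversed, FLO11 at 0.46 without the NBRC1958 array at 60 g/L (-0.39 to 0.47 over what was left out). All 233 values for KF7 against NBRC1958 kept both, as did 221 of 234 for KF7 against NBRC2018, 225 of 236 for NBRC2018 against NBRC1958, 201 of 238 at 60 against 20 g/L and 135 of 144 at 20 against 0 g/L. Of the 107 named genes past the test at 60 against 0 g/L, 6 passed under every alternative, and 10 did with the leave-outs set aside. The alternatives include the fit without the strain block. Without the strain block the counts were 8 for any dose, 66 at 60 against 0 g/L, 0 at 20 against 0 g/L (limma, 158 at unadjusted p under 0.05 with the block) and 4 at 60 against 20 g/L. Without the dose term they were 509 for any strain, 228 for KF7 against NBRC1958, 252 for KF7 against NBRC2018 and 406 for NBRC2018 against NBRC1958. With only the 6 arrays compared, 472, 6 and 373 genes passed for the dose pairs in the order above and 458 for KF7 against NBRC2018. With the lowest 50% left out, which tests fewer genes, 460 passed for any dose, 458 at 60 against 20 g/L, 966 for any strain, and 498 and 337 for KF7 against NBRC1958 and NBRC2018. Asking also for 2-fold gave 119 and 93 genes at 60 against 0 and 20 g/L, and 131, 123 and 124 for the strain pairs. At least 2-fold in each strain were 50 and 39. At least 4-fold at 60 and 20 g/L were 46 and 1 genes in NBRC1958, 33 and 0 in NBRC2018 and 23 and 3 in KF7, and with no level filter KF7 at 20 g/L had 61 at 2-fold. With an estimated correlation 0 lists passed in each of the 7 comparisons (limma camera), and by fry 7, 0, 6, 1, 8, 4 and 0. Leaving out arrays, strains or doses gave 52 to 596 genes for any dose, 98 to 976 at 60 against 0 g/L, 0 to 1 at 20 against 0 g/L, 55 to 714 at 60 against 20 g/L and 234 to 1724 for any strain. It gave 106 to 980 for KF7 against NBRC1958, 104 to 919 for KF7 against NBRC2018, 146 to 1301 for NBRC2018 against NBRC1958, 0 to 1 for any slope and 0 to 3 for the KF7 slope (limma, 421 and 299 at unadjusted p under 0.05 in full). Lists ranged from 11 to 22, 15 to 23 and 16 to 27 for the dose pairs, and from 8 to 20 for the KF7 slope. Slopes with a dose left out could not be fitted, having no residual degrees of freedom. Other than fewer genes or arrays, the cause was not tested.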

Other observations

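The naming of genes in this part was chosen after their values were seen, and no test of an explanation was made. Of 24 haploid and mating genes only STE12, a transcription factor of mating, lay above the level filter, with mean signals of 289 at 0 g/L and 270.1 at 60 g/L (log2 difference -0.05, adjusted p = 0.84). Of 22 meiosis and sporulation genes only IME2 and SGA1 lay above it, and SGA1 had a log2 difference of 0.94 (adjusted p = 0.059). REC102, a gene of meiotic recombination below the level filter, had mean signals of 20.8 at 0 g/L and 74.5 at 60 g/L, with log2 differences of 1.61 in NBRC1958, 0.98 in NBRC2018 and 1.17 in KF7.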
